A study of Mus musculus with 50 samples.

How the data were processed

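The data were gene counts from 3′ mRNA sequencing (QuantSeq FWD) of 50 libraries in 3 sets, each with Cre-positive (TG) and Cre-negative (WT) male mice that had received clozapine N-oxide (CNO) at 1 mg/kg. The sets were whole quadriceps of clamped mice (10 WT, 10 TG), perigonadal white adipose tissue (pgWAT) 1 h after CNO (9 and 9) and pgWAT 6 h after CNO (6 and 6). Per the labels' protocols, RNA was extracted with column kits for lipid tissue (pgWAT) or fibrous tissue with proteinase K (quadriceps) and treated with DNase on the column. The quadriceps and 1 h libraries were made with a second strand module that adds unique molecular identifiers (UMIs) and with dual indices, and the 6 h libraries with the standard kit, so kit and sequencing batch coincide with time in the pgWAT sets. Per the submitters' processing notes the tools were bcl2fastq 2.20.0.422, UMI-tools 1.1.2, cutadapt 1.18 and STAR 2.7.10, listed for all samples without role or order, with the builds GRCm39 and GRCm38. Which build and annotation belong to each table, the counting program and its strand setting, and whether UMIs were collapsed were not given in the sources used here. The deposited values are raw counts per gene without normalization, as whole numbers whose totals differ between libraries.

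The quadriceps and 1 h tables each held 55419 rows, of which 5 were summary lines of reads not assigned to a gene. The 6 h table held 55522 rows, of which 121 were not genes, 114 of these spike-in sequences. Gene rows took a mean of 74.9% of the table's counts in quadriceps and 65.3% in pgWAT at 1 h, where reads in no feature (12.0% and 24.1%) and reads not aligned uniquely (12.6% and 10.1%) made up most of the rest. In pgWAT at 6 h gene rows took 99.8%, and spike-ins 0.0930%. Rows that were not genes were left out of the tests and library totals. Gene identifiers were matched to symbols and positions of GENCODE vM21 on GRCm38. This gave positions to 52081 of 55414 identifiers in quadriceps and pgWAT at 1 h and to 55141 of 55401 in pgWAT at 6 h, and to 8064 of 8070, 11076 of 11087 and 14354 of 14359 tested genes. The tables shared 52338 identifiers.

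Samples were grouped by title. For TG replicate 10 of the quadriceps set the treatment entry of the labels names 1 h while the title says clamped, and the title was followed. Each set was tested on its own as TG minus WT with edgeR 4.0.16 in R 4.3.3, using filterByExpr by genotype, TMM scaling, a robust quasi-likelihood fit, the quasi-likelihood F test and Benjamini-Hochberg adjustment, with a threshold of 0.05 on the adjusted p. This tested 8070, 11087 and 14359 genes, out of 21711, 27814 and 26413 with at least 1 count. Levels are in CPM, counts scaled to a common library total after TMM scaling. The limit for a count of 0 was 3 counts over the gene total of a library or set. Whether the genotype difference differed between the pgWAT times was tested as the interaction of set and genotype in a single edgeR fit over 13022 genes. Shared calls were counted per direction and set beside the number that independent lists of the same sizes would share. DESeq2 1.42.0 was run as an alternative.

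The gene lists, the naming rule and most alternative settings were chosen before the data were examined. The lists were 36, with 580 entries and 527 different genes, of which 23 were programmes and 13 were cell type markers. Lists with at least 5 measured members (27, 28 and 30) were tested with camera of limma 3.58.1 on log CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists tested, and again with an estimated correlation and with fry. In quadriceps the lists past the threshold were the glucocorticoid-induced, heat shock, immediate early, extracellular matrix and slow fibre lists. In pgWAT at 1 h they were the immediate early, cholesterol synthesis, glucocorticoid-induced, interferon and mesothelial marker lists, and in pgWAT at 6 h the glucocorticoid-induced, muscle atrophy and autophagy, and interferon lists. No other list passed in any set. Of the remaining programmes, those of lipogenesis, oxidative phosphorylation, hypoxia, unfolded protein response, glycogen and thermogenic genes had camera adjusted p-values of 0.636, 0.977, 0.610, 0.406, 0.406 and 0.480 in quadriceps. At 1 h these were 0.549, 0.250, 0.126, 0.223, 0.844 and 0.917, and at 6 h 0.629, 0.398, 0.629, 0.994, 0.472 and 0.629. Shorter lists made after the data were seen held liver transcripts (Alb, Ahsg, Serpina1c, Apoa1, Apoa2, Fgb, Ttr and Serpina3k), duct epithelium transcripts (Lrp2 and Cldn10) and inducible heat shock transcripts (Hspa1a, Hspa1b and Dnajb1).

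Genes were named by a rule. Among genes past the threshold with a mean of at least 5 CPM and a symbol that is not a predicted model, the 8 with the smallest p in each direction were taken, and up to 3 members of each list by smallest p. Gfral, Gdf15, Cirbp, Rbm3, Slc2a4, Ucp1, Lep and Adipoq were always named. Some genes that the rule or the lists would bring in are not reported here. For the interaction the 8 with the smallest p were taken under the same filters. The exceptions, chosen after their values were seen, were the 3 predicted genes and Egr1 at 1 h, the interaction values of Txnl1 and Wdr7, the pair of quadriceps and pgWAT at 6 h, Hspa1a, Hspa1b and Dnajb1 in quadriceps, and the genes that open the other observations.

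The test was tested on simulated data with the group sizes and depths of each set, in which 200 genes were changed. Of genes changed 1.5-fold, 2-fold and 4-fold edgeR recovered 68.7%, 89.6% and 95.5% in quadriceps, 46.3%, 85.1% and 93.9% in pgWAT at 1 h, and 65.7%, 76.1% and 97.0% in pgWAT at 6 h, with 5.06%, 3.85% and 3.64% false calls. For the interaction it recovered 17.9%, 59.7% and 93.9% with 2.56% false calls. A moved list was found in each set and 0 unmoved lists were called by camera. The simulated genes were drawn independently, so this cannot show how often camera calls lists of correlated genes. In the real data other splits of the samples called a median of 3, 6 and 6 lists in quadriceps, at 1 h and at 6 h. Libraries were checked for duplicates by the spread of count differences between pairs of a group, and the smallest chi-square per degree of freedom was 1.55 with 0 identical pairs.

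These settings were DESeq2, RLE scaling, no filter on low counts, a fit without robust estimation, the replicate number as a block, the library number's remainder by 8 as a factor, a minimum change of 1.5-fold, other list tests, a z test for the interaction, and leaving out each library in turn. Chosen after seeing the data were leaving out libraries in doubt and scaling by spike-ins. Libraries in doubt were those in which transcripts of other organs, or inducible heat shock transcripts in quadriceps, summed to over 100 CPM and over 5 times the median of the set, with the liver list shortened after all results had been seen. No per-sample column was left unused.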

Results

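Gene expression was measured by 3′ mRNA sequencing, which reads the 3′ ends of polyadenylated transcripts, in 50 libraries from male mice carrying hM3Dq, an engineered receptor through which clozapine N-oxide (CNO) activates neurons. Mice with a Cre recombinase in neurons that express Gfral, the receptor of the hormone GDF15, are called TG, and Cre-negative mice are called WT. Both genotypes received CNO at 1 mg/kg, so each comparison sets TG against WT after CNO, and no group without CNO was sequenced. The libraries came from quadriceps muscle of clamped mice (10 WT, 10 TG), from perigonadal white adipose tissue (pgWAT) collected 1 h after CNO (9 WT, 9 TG) and from pgWAT collected 6 h after CNO (6 WT, 6 TG). Gene counts per library ranged from 959980 to 2613672 in quadriceps, from 976610 to 4852560 in pgWAT at 1 h and from 9150496 to 12883462 in pgWAT at 6 h. At these depths 3 counts, the limit that a count of 0 allows, corresponded to 1.15 to 3.13, 0.618 to 3.07 and 0.233 to 0.328 CPM (counts scaled to a common library total) per library, and this limit covers counting error only. The replicates are numbered in the labels without a statement that each is a separate mouse, so the p-values measure the spread between these samples. Changes are given as log2 of TG over WT with the standard error (SE), group levels as mean ± SD in CPM, and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named.

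Gfral itself, which is expressed in the hindbrain and so cannot check the genotype labels in these tissues, had 0 counts in quadriceps (a limit of 0.120 CPM over the set), 1 count in pgWAT at 1 h and 5 counts in pgWAT at 6 h, the latter in 2 TG libraries. The number of genes that differed between the genotypes was 164 in quadriceps, 8 in pgWAT at 1 h and 2071 in pgWAT at 6 h.

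**Figure D1:**
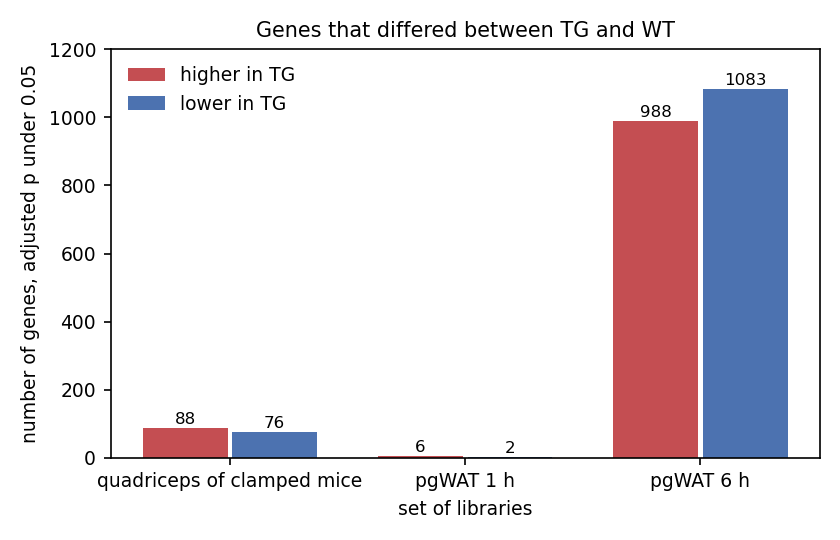
Number of genes with an adjusted p under 0.05 that were higher (red) or lower (blue) in TG than in WT, in each set of libraries. The bars show 88 higher and 76 lower genes in quadriceps, 6 and 2 in pgWAT at 1 h, and 988 and 1083 in pgWAT at 6 h.

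The quadriceps comparison addresses which transcripts changed in a muscle that, per the series description, took up less glucose after activation of these neurons. TG muscle had more transcript of Orm3, an acute phase orosomucoid, of the cold-inducible RNA-binding protein gene Cirbp, of the splicing factor Srsf5 and of the small GTPase Rhob. It had less of Txnl1, a thioredoxin-like proteasome partner, of Ppp1r10, a nuclear regulator of protein phosphatase 1, of Wdr7, a partner of the vesicular proton pump, and of the transcription factor Creb1. Orm3 (ENSMUSG00000028359, chromosome 4, 63356162 to 63359511, positions here and below from GRCm38 with GENCODE vM21) rose from 1.08 ± 1.16 to 18.6 ± 6.28 CPM (n = 10 per genotype), a log2 change of 3.99 (SE 0.32, adjusted p = 1.12e-10, higher in 10 of 10 TG libraries). Its WT mean lay below the 3-count limit, which makes the fold imprecise, and the gene belongs to a family of similar copies between which reads can be shared. Cirbp (ENSMUSG00000045193, chromosome 10, 80165985 to 80172786) rose from 29.4 ± 5.29 to 65.2 ± 13.5 CPM, a log2 change of 1.16 (SE 0.12, adjusted p = 3.94e-08, higher in 10 of 10). Rhob rose by 1.05 and Srsf5 by 1.00 on the log2 scale, with adjusted p-values of 4.21e-10 and 5.32e-10, each in 10 of 10 TG libraries. Txnl1 fell from 190 ± 22.5 to 101 ± 10.3 CPM, a change of -0.90 (SE 0.08, adjusted p = 4.21e-10, lower in 10 of 10). Wdr7 changed by -1.04, Ppp1r10 by -1.31 and Creb1 by -0.58.

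The other transcripts with the smallest p-values were Tiparp, a transcriptional repressor of the aryl hydrocarbon receptor (1.16), the GSK3 inhibitor Frat2 (1.03) and the NF-κB inhibitor Nfkbia (0.56) among those that rose. Among those that fell they were the chromatin remodeller Chd6 (-0.81), the glutathione-degrading enzyme Chac1 (-1.03), the nuclear matrix protein gene Banp (-1.05) and the endoplasmic reticulum protein gene Tmcc1 (-0.41). Their adjusted p-values lay between 6.11e-08 and 8.32e-05, and each difference was in the stated direction in 10 of 10 TG libraries. In total 8070 genes were tested, 88 rose and 76 fell, 81 of the 164 changed by at least 1.5-fold, and 942 had an unadjusted p under 0.05. DESeq2 called 175 genes, 143 of them shared with edgeR. The second principal component, which held 12.2% of the variance, separated all TG from all WT libraries.

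Genes grouped by the fixed lists gave a mixed picture in muscle. Of 23 measured genes of the glucocorticoid-induced list, 6 rose and 3 fell (9 and 3 adjusted over the list alone). Nfkbia and the kinase gene Sgk1 (0.42) rose, and the phosphatase gene Dusp1 fell (-0.83). The list had a median log2 change of 0.15 and passed the camera test upward (adjusted p = 4.35e-04). It did not pass camera with an estimated correlation (adjusted p = 0.283 with an estimated correlation), but it passed fry (adjusted p = 0.00759). Of 21 immediate early genes, Zfp36 rose (0.43) while Dusp1 and Ier3 (-0.86) fell (1 and 6 adjusted over the list alone), with a median of -0.28 and a camera adjusted p of 0.00750 (adjusted p = 0.853 with an estimated correlation). The list call was lost without WT 2 or WT 10 (adjusted p up to 0.168), and the call of Zfp36 without WT 3, 5, 7 or 9 or TG 2 or 5 (adjusted p up to 0.0570). None of the 21 heat shock and chaperone genes passed over all genes in edgeR. Of these 11 had an unadjusted p under 0.05 and 4 were lower adjusted over the list alone. DESeq2 called 2 lower, Hspa1b and Dnajb1. Still 20 of the 21 lay below 0, with a median of -0.27, a mean of -0.61 and a camera adjusted p of 8.34e-06 (adjusted p = 0.842 with an estimated correlation). Without WT 2 and WT 10, which were high in inducible heat shock transcripts, 15 of 21 lay below 0, with a median of -0.14 and a mean of -0.22. The extracellular matrix list (median 0.19) and the slow muscle fibre list (median 0.54) passed upward with a camera adjusted p of 0.0267 each (adjusted p = 0.842 with an estimated correlation for both), and no single member of either passed in edgeR or DESeq2 (unadjusted p under 0.05 in 2 of 12 and 1 of 5). The matrix call was lost without WT 5, 8, 9 or 10 or TG 5 or 6 (adjusted p up to 0.253) and the slow fibre call without WT 3, 4 or 8 or TG 1, 4 or 5 (adjusted p up to 0.117). Thus 5 of 27 lists passed with the preset correlation and 0 with an estimated correlation, while fry called 1, the glucocorticoid list (adjusted p = 0.00759).

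Genes of glucose handling mostly did not pass in muscle. Of 17 measured genes of glucose uptake and glycolysis, Pfkfb3, which makes the activator of phosphofructokinase, rose by 1.00 (SE 0.16, adjusted p = 5.09e-04, higher in 10 of 10), and the other 16 did not pass. Slc2a4, which encodes the insulin-regulated glucose transporter GLUT4, was at 643 ± 83.2 CPM in WT and 623 ± 53.1 CPM in TG, a log2 change of -0.04 (SE 0.07, adjusted p = 0.886). That list had a median of -0.04 and a mean of 0.06, and its camera test pointed up without passing (adjusted p = 0.636). Of 19 insulin signalling genes, the phosphatase gene Ptpn1 rose (0.44) and the insulin receptor substrate Irs1 fell (-0.43), and both calls were fragile. That of Ptpn1 was lost without WT 2, 3, 4, 5, 7 or 9 or TG 2, 4, 6, 7, 8, 9 or 10 (adjusted p up to 0.0861), and that of Irs1 without WT 2, 4, 9 or 10 or TG 2, 4, 5, 6 or 9 (adjusted p up to 0.0653). The Irs1 call was also lost with the replicate block, and both were lost without libraries in doubt. Over alternatives other than single libraries the adjusted p ran from 0.00130 to 0.105 for Irs1 and to 0.0619 for Ptpn1. The mTOR inhibitor Ddit4 (0.49) and the cell cycle inhibitor Cdkn1a (0.80) rose among 23 genes of muscle atrophy and autophagy and Gabarapl1 fell (-0.46). The clock repressor Bhlhe41 rose (0.54) as the single call among 19 clock genes and no gene of 23 for oxidative phosphorylation passed in edgeR or DESeq2, or had an unadjusted p under 0.05 (median 0.01, test down without passing, adjusted p = 0.977). The insulin and clock lists had medians of -0.02 each with tests that pointed up without passing. Adipoq did not pass (-0.12, adjusted p = 0.923), and Rbm3 (187 counts over the set), Ucp1 (310 in WT, 191 of them in 1 library, and 47 in TG), Lep (151) and Gdf15 (14) were too low to be tested. The WT libraries of replicates 2 and 10 stood apart with 2597 and 1505 CPM of the inducible heat shock transcripts Hspa1a, Hspa1b and Dnajb1 summed, against 35.7 to 279 CPM in the other 18, and Hspa1a and Hspa1b are near-identical copies.

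The comparison of pgWAT at 1 h addresses the early response of a depot that, per the series description, took up more glucose. Ddit4 (ENSMUSG00000020108, chromosome 10, 59949669 to 59951834) rose from 110 ± 22.5 to 204 ± 39.1 CPM (n = 9 per genotype), a log2 change of 0.89 (SE 0.12, adjusted p = 0.00103, higher in 9 of 9 TG libraries). Depp1, a FOXO-regulated autophagy gene, rose by 1.21 (SE 0.22) and the stress sensor gene Gadd45g by 0.96 (SE 0.18), each with an adjusted p of 0.0309 and each higher in 9 of 9. Both calls lay near the threshold, with log2 changes of 1.1 to 1.3 for Depp1 and 0.84 to 1.07 for Gadd45g over the fits without single libraries. The call of Depp1 was lost without WT 1, 2, 4, 5, 7 or 9 or TG 1, 2, 3, 5 or 7 (adjusted p up to 0.10), and that of Gadd45g without WT 1, 2, 4, 5, 6, 7 or 9 or TG 1, 3, 5 or 7 (adjusted p up to 0.0920). Both were also lost with the library number's remainder as a factor, with no filter on low counts and without libraries in doubt, and that of Depp1 with the replicate block. Over alternatives other than single libraries the adjusted p ran from 8.99e-05 to 0.639 for Depp1 and from 6.66e-04 to 0.329 for Gadd45g. Txnl1 fell from 113 ± 5.82 to 56.6 ± 5.85 CPM (-1.0, SE 0.08, adjusted p = 4.44e-08), and Wdr7 fell from 41.7 ± 4.65 to 22.9 ± 3.10 CPM (-0.87, SE 0.10, adjusted p = 1.06e-04), both lower in 9 of 9. The remaining 3 genes that rose were the predicted models 4632418H02Rik, Gm44829 and Gm47121, outside the naming rule and named here after their values were seen. In total 11087 genes were tested, 512 had an unadjusted p under 0.05, and DESeq2 called 23 (15 higher, 8 lower), including all 8 of edgeR. Neither of the first 2 principal components separated the genotypes.

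Among the fixed lists at 1 h the glucocorticoid-induced genes had the smallest camera p. Of 21 measured members 20 lay above 0, with a median of 0.21, although Ddit4 alone rose over all genes (5 adjusted over the list alone). The camera adjusted p was 6.72e-10 (adjusted p = 0.149 with an estimated correlation) and that of fry was 0.0495. Of 22 immediate early genes 0 passed in edgeR and 4 had an unadjusted p under 0.05. DESeq2 called 1, Egr1 (1.23, edgeR adjusted p = 0.0958), a gene named after its value was seen. The list had 3 higher genes adjusted over the list alone, a median of 0.18 and a camera adjusted p of 8.73e-06 (adjusted p = 0.523 with an estimated correlation). Mesothelial markers (median 0.84, 7 of 7 above 0, camera adjusted p = 1.42e-04, adjusted p = 0.523 with an estimated correlation) and interferon response genes (median 0.25, camera adjusted p = 0.00246, adjusted p = 0.665 with an estimated correlation) also pointed up. Cholesterol synthesis genes pointed down (median -0.11, camera adjusted p = 0.0218, adjusted p = 0.711 with an estimated correlation). The interferon call was lost without TG 9 (adjusted p = 0.10) and the cholesterol call without WT 1, 2, 4, 5 or 7 or TG 1, 8 or 9 (adjusted p up to 0.327). The 5 of 28 lists that passed with the preset correlation thus became 0 with an estimated correlation, and fry called 2, the glucocorticoid and the hypoxia response lists (adjusted p = 0.0495 each). Ddit4 belongs to both lists and was the only gene past the threshold in either. Of 20 genes of muscle atrophy and autophagy, Ddit4 and Depp1 rose. Slc2a4 (0.16, SE 0.12), Lep (0.03, SE 0.16), Adipoq (0.07, SE 0.14), Cirbp (0.28, SE 0.17) and Rbm3 (-0.21, SE 0.17) did not pass, and Gdf15 (278 counts over the set) and Ucp1 (7 counts) were too low to be tested. Transcripts of other organs stood out in 9 of the 18 libraries, with liver transcripts at 8825 CPM in the TG library of replicate 3 and 2278 CPM in the WT library of replicate 7, against a median of 59.1 CPM. Without the 9 libraries, which leaves 3 WT and 6 TG, Txnl1 alone passed (adjusted p = 0.0281) and Ddit4 did not (0.91, adjusted p = 0.306, against 2.99e-08 at the lowest over its alternatives), and the calls of the immediate early and mesothelial lists were lost.

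At 6 h after CNO the same depot showed a broad change, with the targets of glucocorticoid hormones prominent among the genes that rose. Fkbp5 (ENSMUSG00000024222, chromosome 17, 28399094 to 28517527), a co-chaperone of the glucocorticoid receptor, rose from 51.1 ± 12.3 to 432 ± 52.7 CPM (n = 6 per genotype), a log2 change of 3.08 (SE 0.14, adjusted p = 3.97e-09, higher in 6 of 6 TG libraries). Of the 26 genes on the glucocorticoid-induced list, 23 rose and 0 fell, the same numbers adjusted over the list alone. They included the efferocytosis receptor gene Mertk (1.36) and the arrestin-domain gene Arrdc2 (2.73). The list had a median log2 change of 1.57 and a camera adjusted p of 5.34e-28, and it held with the correlation of its members estimated (adjusted p = 0.00589 with an estimated correlation). The other genes with the smallest p-values were the p53-induced Trp53inp1 (1.78), the kinase gene Hipk1 (1.71), the vesicle priming gene Doc2b (3.96), the scaffold gene Ranbp9 (1.74), Phf11c of the PHF11 family (3.79), Ccdc71l (1.44), the calcium sensor gene Stim1 (1.38) and Fam129b (1.68), with adjusted p-values from 3.39e-10 to 1.75e-09. Lower in TG were the transcription factors Dmrt2 (-1.44), Hoxc6 (-1.12) and Irf1 (-0.96), the immune checkpoint ligand Cd274 (-1.71), the insulin receptor substrate Irs3 (-1.71), Txnl1 (-0.81), Pwwp3a (-0.81) and Cxxc5 (-1.39), with adjusted p-values from 6.71e-08 to 6.03e-07. Each of these was in the stated direction in 6 of 6 TG libraries.

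**Figure D2:**
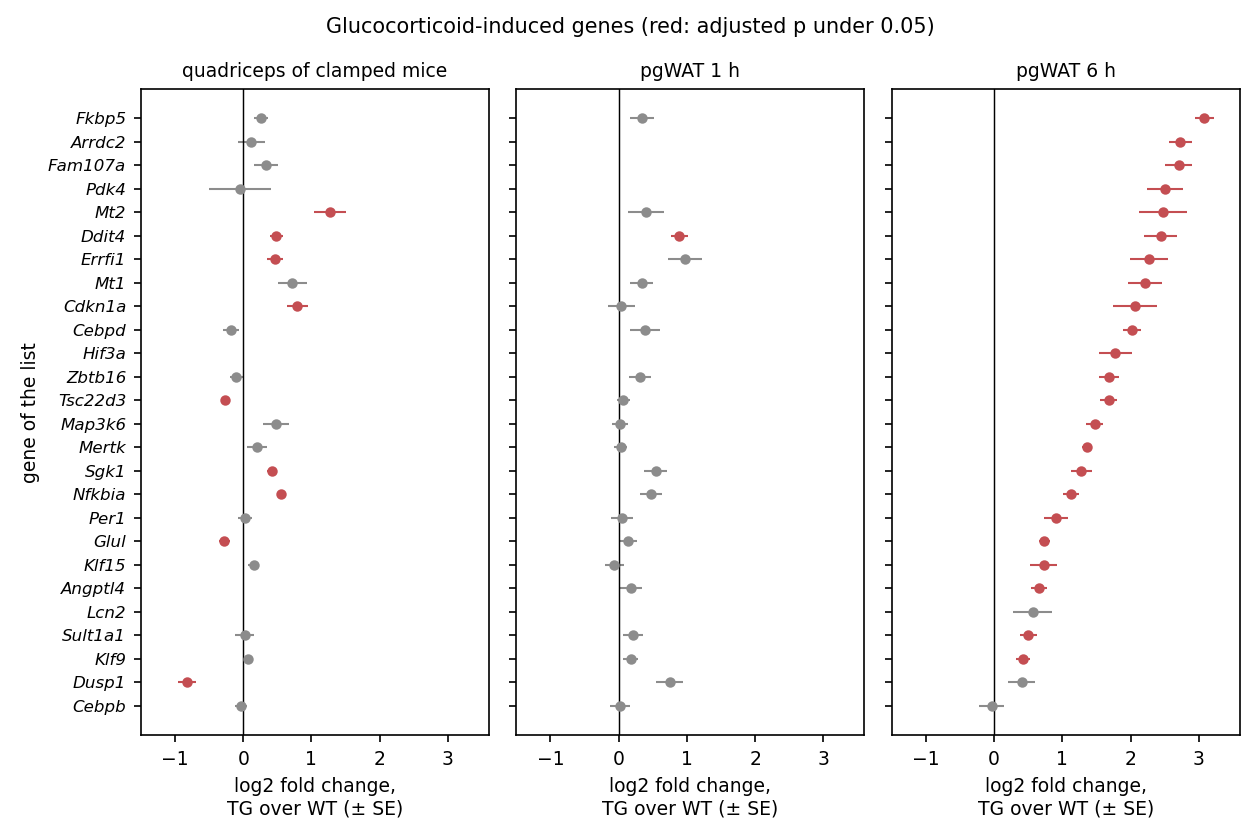
Log2 fold change of TG over WT (points, with bars of 1 SE) for the genes of the glucocorticoid-induced list in quadriceps, pgWAT at 1 h and pgWAT at 6 h, with red points for an adjusted p under 0.05 and no point where a gene was too low to be tested. In pgWAT at 6 h 23 of the 26 genes rose, against 1 of 21 at 1 h, and in quadriceps 6 of 23 rose and 3 fell.

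Other groups shifted in part at 6 h. Of 20 genes of muscle atrophy and autophagy, 10 rose and 1 fell (11 and 1 adjusted over the list alone). The FOXO transcription factor genes Foxo1 (1.00) and Foxo3 (0.67) and Ddit4 (2.44, from 45.2 ± 20.7 to 245 ± 22.1 CPM) were among those that rose. That list had a median of 0.23 and a camera adjusted p of 3.02e-05 (adjusted p = 0.113 with an estimated correlation). It shares members with the glucocorticoid-induced list, Ddit4 and Cdkn1a among them, so the 2 calls are not separate. Of 18 interferon response genes 8 fell and 0 rose (11 and 0 adjusted over the list alone), among them Gbp3 (-0.85) and the immunoproteasome subunit Psmb8 (-0.50), with a median of -0.55 and a camera adjusted p of 3.02e-05 (adjusted p = 0.790 with an estimated correlation). Lymphocyte markers lay on the same side (median -0.58, 0 of 5 above 0, camera adjusted p = 0.472). Neutrophil markers were mixed, with Mmp9 lower (-1.29) and 1 of 4 above 0 (median -0.91, not tested as a list), and their summed level was 43.4 ± 13.7 CPM in WT and 45.3 ± 23.5 CPM in TG. The glucocorticoid-induced, muscle atrophy and autophagy, and interferon lists were the 3 of 30 lists that passed with the preset correlation. All 3 passed by fry, and the glucocorticoid list alone passed with an estimated correlation. Fatty acid oxidation and extracellular matrix genes did not pass (camera adjusted p = 0.0510 each, adjusted p = 0.998 each with an estimated correlation, and 0.200 and 0.262 by fry), with Pdk4, which restrains glucose oxidation (2.50), and the basement membrane collagen Col4a1 (0.59) higher and the mitochondrial carrier Ucp3 (-1.69) lower.

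Genes of fat metabolism and of insulin action changed in both directions, and their lists did not pass for a shared direction. The β3-adrenergic receptor gene Adrb3 fell from 672 ± 245 to 147 ± 54 CPM (-2.20, SE 0.32, adjusted p = 9.92e-04, lower in 6 of 6), and the lipase inhibitor G0s2 fell (-1.48) among 20 lipolysis and lipid droplet genes, of which 3 rose and 4 fell (3 and 5 adjusted over the list alone). The adipocyte regulator Pparg fell from 172 ± 12.0 to 85.1 ± 14.8 CPM (-1.01, SE 0.10, adjusted p = 2.09e-06, lower in 6 of 6), and the lipogenic regulators Srebf1 (-0.55) and Mlxipl (-0.62) fell while the phosphatidate phosphatase gene Lpin1 rose (0.71). In glucose uptake and glycolysis, hexokinase Hk2 (-0.73) and Pfkfb3 (-1.31) fell among 21 genes and the glucose transporter gene Slc2a1 rose (0.45, adjusted p = 0.0326), a call lost without WT 2, 3 or 5 or TG 2, 5 or 6 (adjusted p up to 0.0790), with the replicate block, with spike-in scaling and without libraries in doubt (0.0168 to 0.0759 over its alternatives). Slc2a4 did not pass (0.15, SE 0.09, adjusted p = 0.300). In insulin signalling Irs1 (-1.11) and Irs2 (-0.996) fell, with 1 higher and 4 lower of 20. Clock genes split, 6 up and 4 down of 20 (8 and 4 adjusted over the list alone), with Bhlhe40 (-1.87) and Bhlhe41 (-1.58) lower and Cry2 (0.57) higher. Of 28 immediate early genes 5 rose, including the matrix-associated Ccn1 (2.08) and the AP-1 component Fosl2 (1.11), and 2 fell, including Jund (-0.55). The adipokine enzyme gene Nampt rose (1.12) and the peptide hormone gene Apln fell (-1.82), a call lost with the replicate number as a block (adjusted p = 0.0786, against 1.06e-05 at the lowest over its alternatives). None of these lists passed camera, which tests for a shared direction. In fry's test for changes in either direction the unadjusted p was 2.88e-12 for lipolysis, 5.43e-08 for glucose uptake and 1.69e-11 for insulin signalling. That test does not set a list against the other genes, and 2071 of all 14359 genes passed in this set. The lists of lipolysis, glucose uptake and insulin signalling had medians of 0.02, 0.07 and 0.00 with means of -0.16, -0.04 and -0.12.

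The cold-inducible gene Cirbp rose at 6 h from 52.2 ± 6.48 to 88.7 ± 11.8 CPM (0.76, SE 0.09, adjusted p = 2.59e-05, higher in 6 of 6). Its relative Rbm3 rose from 9.34 ± 1.47 to 12.6 ± 1.81 CPM (0.43, SE 0.13, adjusted p = 0.0338, higher in 6 of 6), a call that was lost without WT 2, 4, 5 or 6 or TG 1, 2, 4 or 6 (adjusted p up to 0.0767), with no filter on low counts, with spike-in scaling and without libraries in doubt (0.0163 to 0.110 over its alternatives). Lep (0.65, SE 0.32, adjusted p = 0.233, higher in 6 of 6), Adipoq (-0.09, SE 0.09, adjusted p = 0.578) and Gdf15 (-0.08, SE 0.50, adjusted p = 0.942) did not pass, and Ucp1 had 14 counts over the set. None of the cell type marker lists with at least 5 measured members passed camera, and the shorter ones were not tested. Medians were farthest from 0 for neutrophil (-0.91), satellite cell (0.78), myofibre (0.63), lymphocyte (-0.58) and erythrocyte markers (0.39), on 2 to 5 genes each. Single markers did pass, with the macrophage scavenger receptor Cd163 (0.80) and the myofibre actin Acta1 (1.26, from 34.2 to 81.8 CPM) higher, and the endothelial receptor Tek (-0.56) and the myelin gene Mbp (-0.60) lower. Of 10 endothelial markers 8 lay above 0 (median 0.09), and Flt1 rose (0.32, adjusted p = 0.0329), a call lost without any of the 6 WT libraries or TG 3 (adjusted p up to 0.0672) and with spike-in scaling (0.0189 to 0.0522 over its alternatives). Liver transcripts reached 1445 CPM in the TG library of replicate 2 against 43.9 to 77.2 CPM in the other 11. In total 14359 genes were tested, 988 rose and 1083 fell, 1042 changed by at least 1.5-fold, and 3821 had an unadjusted p under 0.05. DESeq2 called 2436 genes, including all 2071 of edgeR. The first principal component, with 33.5% of the variance, separated all TG from all WT libraries.

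A direct test of whether the genotype difference in pgWAT differed between 1 h and 6 h addressed the time course. The libraries of the 2 times also differed in kit, in the use of molecular identifiers and in depth, so time and library batch cannot be told apart. The change of Hipk1 was larger at 6 h than at 1 h by 1.65 on the log2 scale (SE 0.13, adjusted p = 4.73e-10), that of Fkbp5 by 2.73 (SE 0.24, adjusted p = 3.51e-09) and that of Mertk by 1.33. The same held for Ccdc71l (1.51), the neuronal reprimo-like gene Rprml (2.27), Phf11c (4.29), Ranbp9 (1.74) and Fam129b (1.67). At 1 h Fkbp5 itself did not pass (0.35, SE 0.17), and Phf11c was too low to be tested there. Of 13022 genes tested, 548 passed, 244 with a more positive and 304 with a more negative change at 6 h, and 511 of them had also passed at 6 h and 3 at 1 h. DESeq2 called 774, a z test of the separate fits 890 and the fit without libraries in doubt 319, and in the main fit 1984 had an unadjusted p under 0.05. On the glucocorticoid-induced list 14 of 26 genes passed, all 14 more positive at 6 h, with a median difference of 1.32. Of 18 interferon response genes 4 passed, all more negative at 6 h. Neither Txnl1 (0.19, SE 0.10, adjusted p = 0.359) nor Wdr7 (-0.16, SE 0.15, adjusted p = 0.713) passed, and both were chosen for this test after their values were seen.

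Shared changes across the sets address which genotype differences recur between times and tissues. The quadriceps came from clamped mice, while the pgWAT sets are labelled by time after CNO and not as clamped. Tissue, clamp and time therefore cannot be told apart between muscle and fat. Ddit4, Gadd45g, Txnl1 and Wdr7 passed in the same direction in all 3 sets, with Ddit4 and Gadd45g higher and Txnl1 and Wdr7 lower in TG. At 1 h the call of Gadd45g was lost in 11 of 18 fits without a single library. Without libraries in doubt, which leaves fewer samples, Txnl1 alone passed at 1 h and was the 1 gene shared with either other set. Between pgWAT at 1 h and 6 h 7 genes were shared, these 4 and Depp1, 4632418H02Rik and Gm47121, where independent lists of these sizes would share 0.628. Between quadriceps and pgWAT at 1 h the 4 genes were shared, against 0.0604 from independent lists. Quadriceps and pgWAT at 6 h, a pair added after the data were seen, shared 45 genes in the same direction, against 11.9 from independent lists, and 18 passed in opposite directions, against 11.6. Whether the sets share mice is not stated in the labels, and if they do, the numbers from independent lists do not apply. Those numbers also treat genes as independent, which neighbours such as Txnl1 and Wdr7 may not be. Cirbp, Rhob, Tiparp, Frat2, Srsf5 and Nfkbia rose in both quadriceps and pgWAT at 6 h. Creb1, Banp and Irs1 fell in both, with the fragile call of Irs1 in quadriceps. Pfkfb3 and Bhlhe41 were among the genes with opposite directions. Txnl1 (ENSMUSG00000024583, chromosome 18, 63661094 to 63708801, minus strand) and Wdr7 (ENSMUSG00000040560, chromosome 18, 63708685 to 63989776, plus strand) lie head to head and overlap by 117 bp. At 6 h Txnl1 fell from 59.7 ± 2.53 to 34.0 ± 2.56 CPM and Wdr7 from 19.7 ± 1.48 to 9.59 ± 1.60 CPM (-1.03, SE 0.11, adjusted p = 7.08e-06), and for both genes every TG library lay below every WT library in all 3 sets.

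**Figure D3:**
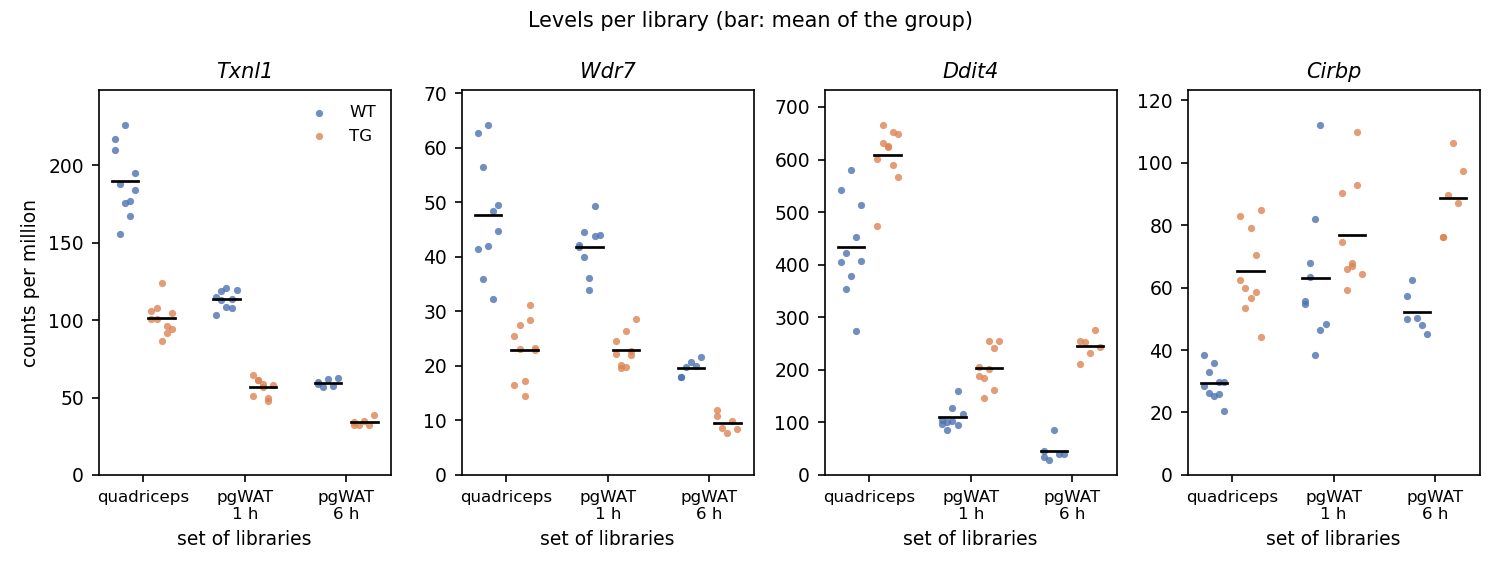
Level in CPM of Txnl1, Wdr7, Ddit4 and Cirbp in each WT (blue) and TG (orange) library of the 3 sets, with a black bar at the mean of each group. Txnl1 and Wdr7 were lower in every TG library than in every WT library of the same set, Ddit4 was higher in TG in all 3 sets, and Cirbp passed in quadriceps and in pgWAT at 6 h but not in pgWAT at 1 h.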

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

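The tests of the Txnl1 and Wdr7 locus and of the heat shock genes were chosen after those results were seen, and so were the lists of liver, duct epithelium and inducible heat shock transcripts, the look at spike-ins and the test of libraries with transcripts of other organs against 6 h libraries of the same number, while the tests of sequencing depth and of other splits of the samples were set down before their values were seen.

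The genotype difference in pgWAT differed between 1 h and 6 h by a direct test in 548 genes, 244 more positive and 304 more negative at 6 h, and the 8 named genes with the smallest p were all more positive. Fkbp5, the co-chaperone of the glucocorticoid receptor, differed by 2.73 on the log2 scale and the phagocytic receptor gene Mertk by 1.33. The difference was 1.65 for Hipk1, 1.51 for Ccdc71l, 2.27 for Rprml, 4.29 for Phf11c, 1.74 for Ranbp9 and 1.67 for Fam129b. Phf11c has near relatives beside it, so its reads are uncertain, and time coincides with library kit for all 8 genes.

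Libraries far from the others of their group were looked for by the gap of the highest or lowest library to its neighbour, as a share of the group's range. Of 270 groups of values 23 stood out, where chance gives about 1 in 20, or 13.5. In 13 of the 23 the value was that of a named gene. In quadriceps, Dusp1 was highest in WT 10 (gap share 0.539) and Ddit4 was lowest in TG 1 (0.529). In pgWAT at 6 h, TG 5 was highest for Fosl2 (0.762), Irs2 (0.699), Atf4 (0.763) and Flt1 (0.725), and for the summed inducible heat shock transcripts (0.756, at 83.6 CPM). In the same set TG 1 was lowest for Ndrg1 (0.739) and Adipoq (0.706), and TG 2 was highest for Ppp1r3b (0.717). Among WT libraries at 6 h, WT 3 was highest for Irs2 (0.663) and lowest for Flt1 (0.690), and WT 5 was highest for Egfl7 (0.643) and Notch3 (0.639).

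Transcripts of other organs and library totals accounted for the other libraries that stood apart. Liver transcripts were highest in quadriceps WT 2 (gap share 0.992, 232 CPM against 1.92 CPM in the next) and TG 7 (0.543, 3.91 CPM). In pgWAT at 1 h they were highest in WT 7 (0.789, 2278 CPM against 511 CPM) and TG 3 (0.993, 8825 CPM against 82.9 CPM), and at 6 h in TG 2 (0.982, 1445 CPM against 74.1 CPM). Duct epithelium transcripts were highest in WT 9 at 1 h (0.545, 261 CPM against 120 CPM) and in WT 1 at 6 h (0.675, 17.8 CPM). Gene counts were highest in quadriceps WT 6 (0.640, 2613672 counts) and in 1 h TG 8 (0.539, 4852560 counts). Spike-in sequences, used only for a scaling of the 6 h set chosen after seeing the data, had counts in every library of the 6 h set, the lowest being 8194 in TG 3, with 8871 to 11350 in WT and 8194 to 12389 in TG.

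Txnl1 and Wdr7 were lower in TG in all 3 sets, by -0.81 to -1.04 on the log2 scale, with every TG library below every WT library. Reads shared between these overlapping genes are argued against by the distance of their annotated 3′ ends, where the kit's reads start, of 329 kb. A response that builds up from 1 h to 6 h is argued against, since the time difference of both genes plus 2 standard errors stayed at or below 0.45. A change at the locus carried with the Cre line is a candidate explanation. Of the 7 other genes within 1 Mb that were tested in 2 or more sets, 0 passed in the same direction in 2 or more. An effect of neuron activation on Txnl1 and Wdr7 alone would also leave the neighbours unchanged, so this value favours neither explanation. A direct effect of neuron activation on these genes stays open, because every mouse received CNO and no DNA was read, and Gfral lies on another chromosome, 9.

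Far more genes passed in pgWAT at 6 h (2071) than at 1 h (8). Sequencing depth is argued against as the whole cause, since 6 h libraries thinned to totals of 1 h libraries still gave 1042 genes, 965 of them shared with the full 6 h libraries. Spread at 1 h from libraries with transcripts of other organs is argued against as the whole cause as well. Without 9 such libraries (3 WT and 6 TG left) the count at 1 h was 1, while 20 choices of 3 WT and 6 TG libraries of the 6 h set, thinned to the same totals, gave 507 to 924 genes. The 1 h libraries stayed more variable without the 9. Their biological coefficient of variation, edgeR's measure of spread between libraries, was 0.194, against 0.132 in the full 6 h set after thinning. Larger spread at 1 h from other sources was not tested. The library kit and its molecular identifiers coincide with time and cannot be told apart from it. A response that grows between 1 h and 6 h is left open as a hypothesis.

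Heat shock and chaperone genes were lower in TG quadriceps as a list, with 20 of 21 below 0. A few WT libraries as the source cannot be told apart from genotype: without WT 2 and WT 10 the adjusted p of the list was 0.00827 (0.938 with an estimated correlation; over its alternatives other than single libraries left out, 5.40e-07 to 0.842), the median went from -0.27 to -0.14 and the mean from -0.61 to -0.22, and 15 of the 20 stayed below 0. Cell makeup of the sample cannot be told apart either, since the smallest adjusted p of the cell type marker lists other than myofibre was 0.480. Spread of the list between mice of any grouping is a candidate explanation, since 11 of 100 splits of the quadriceps libraries gave the list as small a p. The verdicts on the WT libraries and on cell makeup were changed after the value with an estimated correlation was seen, and the split test was added after the result and the split counts were seen.

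Other splits of the samples show how often a chance division gives as many calls. For genes in quadriceps 1 of 100 splits, the real one, gave as many as the 164 genes (highest other 1). At 6 h 1 of 100 gave as many as 2071 (highest other 13), and for the interaction 1 of 100 as many as 548 (highest other 3). With 100 splits the share cannot fall below 1 in 100, so chance is unlikely here rather than excluded. Other splits also mix the genotypes, so a genotype difference widens their spread and lowers their counts. For the shared genes 1 of 100 pairs of splits gave as many as the 7 of pgWAT at 1 h and 6 h, and 1 of 100 as many as the 4 of quadriceps and pgWAT at 1 h (highest other 0 each). Other splits called a median of 0 genes and so had next to nothing to share, which leaves chance sharing undecided by these pairs. For genes in pgWAT at 1 h 3 of 100 splits, the real one among them, gave as many as 8, a share under the limit set beforehand. This test judges the count and not single genes. Chance is still not excluded for a count of 8, since the highest other split called 62 genes. What set that split apart was not tested. For the number of lists chance is not excluded: 39 of 100 splits gave as many as 5 in quadriceps (highest other 16), 60 of 100 as many as 5 at 1 h (highest other 15) and 88 of 100 as many as 3 at 6 h (highest other 14). List by list, the glucocorticoid-induced genes gave as small a p in 2, 1 and 1 of 100 splits in quadriceps, at 1 h and at 6 h. The muscle atrophy and autophagy list did so in 2 at 6 h, and the other lists that passed in 7 to 38. These numbers include the real split. For the glucocorticoid list the smallest unadjusted camera p of another split was 1.65e-05, 4.69e-10 and 1.08e-20 in the 3 sets. Camera p-values with the preset correlation can thus be very small in other splits too.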

How the results depend on the processing

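Alternatives chosen after seeing the data were leaving out libraries in doubt and scaling by spike-ins. Over 158 results and 3517 values under alternatives, 0 changed direction with a call. Of the values 3269 kept their side of the threshold or, for counts, stayed within 1.5 times, and direction was not compared where neither fit passed. Another 205 fell short of the threshold, 0 newly passed it and 43 counts moved by over 1.5 times. The 0 was largely fixed beforehand, since the tally held only lists that had passed and named genes that mostly had. Outside it some did newly pass, such as the hypoxia list by fry and Egr1 by DESeq2 at 1 h. Where no reason is given, the cause was not tested.

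By construction a minimum of 1.5-fold left 81 of 164 genes in quadriceps and 1042 of 2071 at 6 h, and 8 at 1 h. At 1 h the 8 genes became 23 with DESeq2, 5 with no filter on low counts, which tests more genes, 3 with the library number's remainder as a factor and 1 without libraries in doubt, which leaves fewer samples, and 8 and 12 with RLE scaling and without robust estimation. The z test of the separate fits gave 890 interaction genes against 548, and leaving out libraries in doubt gave 319. Shared genes of pgWAT at 1 h and 6 h went from 7 to 12 with DESeq2, 4 with no filter and 1 without libraries in doubt, and those of quadriceps and 1 h from 4 to 1 without libraries in doubt. Camera with an estimated correlation called 0 lists in quadriceps, 0 at 1 h and 1 at 6 h, and fry called 1 in quadriceps and 2 at 1 h. At 6 h 3 lists became 5 with RLE scaling, with no filter and without libraries in doubt. Scaling by spike-ins gave 698 higher and 1121 lower genes at 6 h, 38.4% higher against 47.7% with TMM, with a median log2 change of -0.03. The list of liver transcripts that helps to define libraries in doubt was shortened after all results had been seen. With the longer list 7 libraries at 1 h were in doubt where the shorter list gives 9, and without those 7 Ddit4 and the mesothelial marker list kept their calls, which they lose without the 9. The immediate early list lost its call at 1 h with either list.

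Without single libraries the counts ranged from 123 to 198 genes in quadriceps, 1666 to 2091 at 6 h and 439 to 610 for the interaction. At 1 h they ranged from 3 to 12, with 3 without WT 1, WT 2, WT 7 or TG 3, and 5 without WT 4, WT 5, WT 9, TG 1, TG 5 or TG 7. Lists ranged from 3 to 5 in quadriceps (3 without WT 8, WT 10 or TG 5), from 3 to 8 at 1 h (8 without TG 4, 3 without TG 9) and from 3 to 7 at 6 h (7 without TG 1, 5 without WT 2, WT 3, TG 2, TG 3 or TG 4). Of named genes past the threshold 24 of 28 in quadriceps, 3 of 5 at 1 h, 72 of 84 at 6 h and 8 of 8 for the interaction stayed past it without any single library.

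The replicate numbers do not pair the samples: correlations of WT and TG libraries of the same number ran from -0.22 to 0.23 in quadriceps, -0.25 to 0.39 at 1 h and -0.08 to 0.11 at 6 h, and 1, 1 and 0 WT libraries matched best with their own number. With a replicate block 144, 5 and 1874 genes passed in the 3 sets, and 4 genes were shared between pgWAT at 1 h and 6 h. The depth at 1 h and in quadriceps limits what can be seen of genes with few counts, such as Gdf15 and Rbm3.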

Other observations

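The genes below were chosen after their values were seen, as those with large changes that the naming rule left out, and no test was added for them.

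In quadriceps the transcription factor gene Sox4 rose from 38.1 to 278 CPM (n = 10 per genotype, log2 2.77, SE 0.27, edgeR adjusted p = 3.62e-06, higher in 10 of 10), and Frat1, the relative of Frat2, rose by 1.34. The metallothionein gene Mt2 rose from 493 to 1192 CPM. The myogenic factor gene Myod1 fell from 46.7 to 21.4 CPM (-1.11), and the calcineurin inhibitor Rcan1 fell by 1.35 on the log2 scale with an adjusted p of 0.0459, both lower in 10 of 10.

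In pgWAT at 6 h the small GTPase Rasd1 fell from 132 to 5.31 CPM (n = 6 per genotype, -4.63, SE 0.31, edgeR adjusted p = 1.94e-06, lower in 6 of 6), and the lactate receptor gene Hcar1 fell from 78.7 to 20.4 CPM (-1.95). The melanocortin receptor gene Mc5r rose from 1.13 to 11.5 CPM (3.32), and the arrestin-domain gene Arrdc3 from 28.8 to 147 CPM (2.35). Mt2 rose from 992 to 5507 CPM, and Setdb2, a histone methyltransferase gene next to the Phf11 family, from 2.96 to 38.2 CPM (3.69). The immunoglobulin genes Iglc3 (-3.49) and Jchain (-1.94) fell.

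Transcripts that liver or duct epithelium make in abundance were summed from lists made after seeing the data. In quadriceps liver transcripts lay between 0 and 3.91 CPM apart from WT 2. In pgWAT at 1 h duct epithelium transcripts ranged from 2.41 to 312 CPM, highest in TG 4 (312 CPM), TG 6 (281 CPM) and WT 9 (261 CPM), against a median of 15.2 CPM, and at 6 h from 3.82 to 18.7 CPM. Summed mesothelial markers at 1 h were 148 ± 93.1 CPM in WT and 257 ± 161 CPM in TG (SD, n = 9 per genotype).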
